A study of Mus musculus with 15 samples.

How the data were processed

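RNA was measured in Peyer's patches, the lymphoid follicles of the small intestinal wall, and in mesenteric lymph nodes, which drain the intestine. The tissues came from C57BL/6J mice that were uninfected or had been given Yersinia enterocolitica by mouth. Per the labels, tissue of 10 mice was pooled for each time point, total RNA was isolated with Trizol, and labelled material was hybridised to Affymetrix MGU74Av2 arrays, which carry sets of oligonucleotide probes against mouse transcripts. Both tissues were taken from uninfected mice and at 12 hours and days 2, 4 and 7 of infection. Each of the 5 Peyer's patch groups had 2 arrays and each of the 5 lymph node groups had 1 array, 15 arrays in all. The number of arrays limits the precision of every value.

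Groups were taken from the sample titles. The description field calls every Peyer's patch sample uninfected, which conflicts with those titles. 1 of the 12-hour Peyer's patch arrays has no replicate number in its title and was taken as the first. The labels do not say whether the 2 arrays of a group came from separate pools of mice. The p-values therefore measure the spread between arrays, which may be technical, and not the spread between animals.

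The deposited values are linear signal intensities, 1 for each probe set and array, which the authors made with MAS5, per the submitters' processing notes. The version, the scaling target and any filtering are not given in the sources used here. The values ran from 0 upwards, and their mean after 2% trimming lay between 148 and 148.8 on all 15 arrays, as it does when arrays are scaled to a common mean. Among the 12422 probe sets, 0 carried the manufacturer's prefix for control sequences, so RNA quality could not be read from such controls.

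Signals were transformed as log2(signal + 32), which damps ratios between dim signals. The dimmest 40% of probe sets by mean over the arrays of a fit were left out, which left 7453 probe sets and corresponded to a mean signal of 37.5 in Peyer's patches. Group means of the 10 Peyer's patch arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 5 residual degrees of freedom and a prior of 4.6. Each infected group was compared with the uninfected group, neighbouring times were compared with each other, and a moderated F test asked for a difference from uninfected at any time. Tissues were compared with the same tool on the 5 Peyer's patch condition means and the 5 lymph node arrays, with condition as a block and 4 residual degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the probe sets tested. A probe set was called at an adjusted p under 0.05. In the lymph node, with 1 array per group, no p-value was computed. There the probe sets with at least a 2-fold difference from the uninfected array were counted.

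Probe sets were paired with genes through the annotation table given with the series. In it, 10833 probe sets had 1 gene, 396 had several and 1193 had none. Of the first, 10817 matched a gene of the RefSeq table by Entrez identifier, 0 symbols changed, and 8251 genes resulted. No genome was used, so no coordinates are given. Probe sets whose names end in _f_at, _s_at, _g_at, _i_at or _r_at can share sequence with other transcripts or break the manufacturer's design rules.

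Lists of genes for immune and intestinal cell types, immune responses, stress and metabolism, 32 in all, were tested with limma's camera at a preset correlation between genes of 0.01, where at least 5 members were measured. Each gene entered by its brightest probe set. The lists held 825 entries with a current gene symbol, where a gene on several lists counts in each. Not all of these were measured, as with the ribosomal protein genes, of which 23 of 68 entered the Peyer's patch tests. Camera asks whether a list moved against the other genes, and its p-values were adjusted over the lists. It was repeated with a correlation estimated from the arrays. The fry test, which asks whether the genes of a list moved on balance one way without comparing them with other genes, was also run. Counts of list members past the threshold are given over all probe sets and adjusted over the list alone. In the lymph node, a list's median log2 ratio was ranked among the medians of 10000 random lists of the same size matched on mean signal. The genes of these random lists were drawn independently, so the percentile does not allow for members that vary together.

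Genes were named by a rule. For each Peyer's patch comparison it took the 10 rising and the 10 falling genes with the largest change among those past the threshold in which both arrays of the 1 group lay on the same side of both arrays of the other. It further took 2 to 4 members of each list described with the largest change, the 8 highest and the 8 lowest genes at each lymph node time, 10 genes in each direction between tissues, and a fixed panel of cytokine, interferon and lymphocyte genes. The text leaves out some of these. Genes named outside the rule are said to have been chosen after their values were seen.

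The groups, tests, filter, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 8 and 100, no filter or a stricter one, median centring and quantile normalization, other variance models, a threshold of 0.01, fits on the arrays of 2 groups alone, a block for the replicate number, other probe sets of a named gene, and leaving out each array in turn. A fit without the first arrays of days 4 and 7 was added after the data were seen. The procedure was tested on simulated data. For day 2 against uninfected Peyer's patches, with 200 of 7453 probe sets changed in each of 20 runs, 98.6% of 4-fold and 61.5% of 2-fold changes were recovered and 5.55% of calls were false. For the comparison of tissues these values were 100%, 98.4% and 6.68%. A shift of 0.5 log2 units in a list of 25 genes was recovered in 20 of 20 runs at day 2, with 2 false calls among 540 tests of unshifted lists. These runs drew noise independently for each probe set, with the same spread in every group. On the real arrays the SD of the log2 difference between replicates was 0.25 at day 2 and 0.63 at day 7. The runs held neither such unequal spread nor correlated genes, so their rates may not hold for the real calls. Figures were drawn with Python 3.11.15.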

Results

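The series followed RNA levels in 2 intestinal lymphoid tissues of the mouse over the first week of an oral infection with Yersinia enterocolitica, a bacterium that enters the body through the epithelium covering Peyer's patches. Peyer's patches were measured on 2 arrays in each of 5 groups, which were uninfected, 12 hours, day 2, day 4 and day 7. Mesenteric lymph nodes were measured on 1 array in each of the same 5 conditions. Each array gave a signal for 12422 probe sets, with a median between 51.5 on the first day 7 Peyer's patch array and 74 on the uninfected lymph node array. Signals below are means ± SD of n = 2 arrays in Peyer's patches and single values in the lymph node. Changes are log2 differences of (signal + 32) with their standard errors (SE), and adjusted p-values are from limma.

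Across probe sets, the 2 arrays of a Peyer's patch group correlated with r of 0.976 for uninfected, 0.97 for 12 hours, 0.981 for day 2, 0.945 for day 4 and 0.899 for day 7. These correlations are across genes, which are not independent replicates. The arrays of day 7 differed at least 2-fold at 604 probe sets, those of day 4 at 188, and those of the other groups at 39 to 76. In Peyer's patches 532 of 7453 probe sets differed from uninfected at any time. That count was 245 and 254 without the first and second uninfected array, 275 and 285 without either 12-hour array, and 232 and 240 without either day 2 array. It was 974 and 1940 without the first and second day 7 array.

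**Figure D1:**
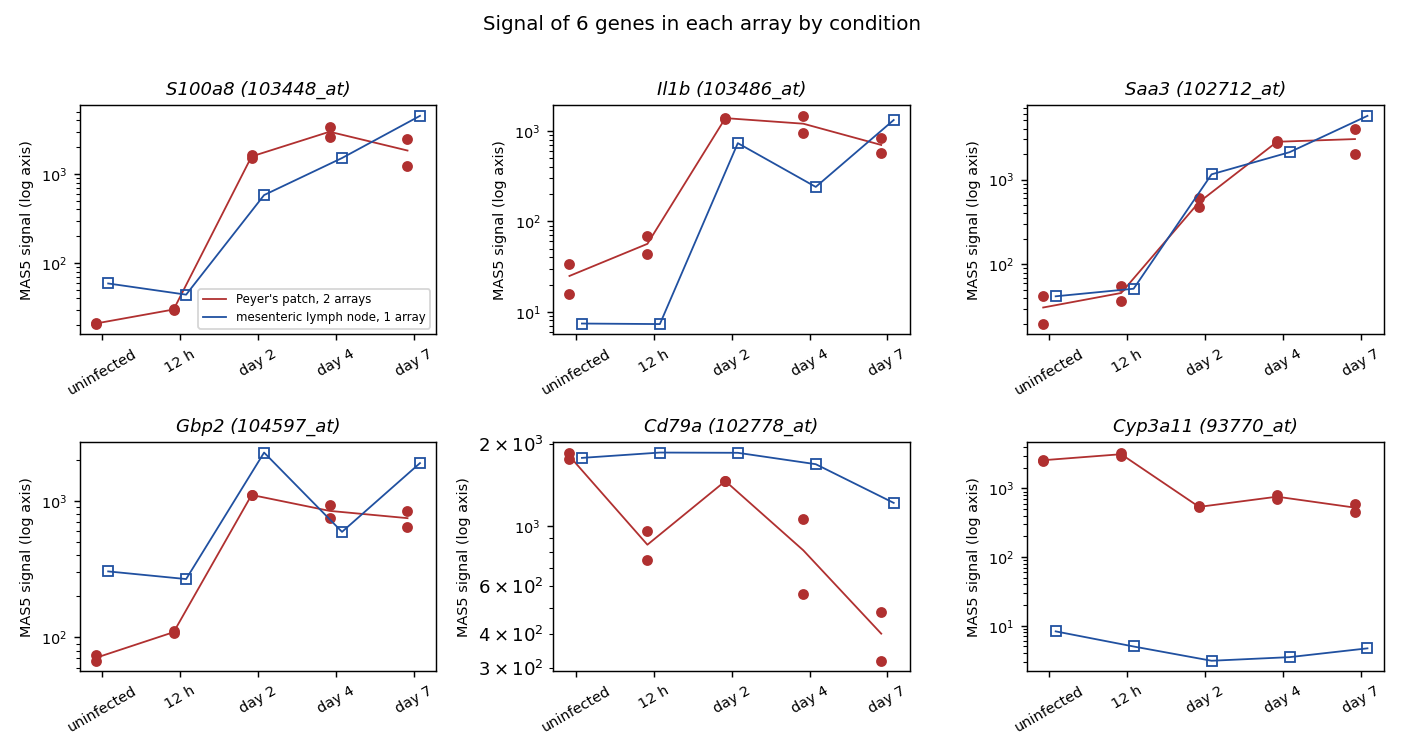
MAS5 signal (log axis) of 6 genes against time, with the 2 Peyer's patch arrays of each group as red dots joined through their mean and the single lymph node array as open blue squares. In Peyer's patches S100a8 went from 20.9 in uninfected tissue to 1580 at day 2 and 2990 at day 4, while Cd79a went from 1800 to 402 at day 7.

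The first comparison asked how Peyer's patches 12 hours into the infection differed from uninfected ones. Sgk1, a kinase whose gene is induced by serum and glucocorticoids, rose by 2.20 (SE 0.22, adjusted p = 0.0045), from a signal of 270 ± 53 to 1340 ± 87. Abcb1a, a drug efflux pump of the intestinal epithelium, rose from 265 ± 9 to 945 ± 58 (log2 change 1.72, adjusted p = 0.0086). The transcription factor Zbtb16 rose from 2.15 ± 2.2 to 70.6 ± 4.5, and the immediate early gene Fos from 360 ± 34 to 1000 ± 110. Slc34a2, a sodium phosphate transporter of epithelia, fell from 1320 ± 81 to 305 ± 17 (log2 change -2, SE 0.18, adjusted p = 0.0022). Sprr2b, which encodes a small proline-rich protein of epithelia, fell from 9200 ± 130 to 2990 ± 210, and Vpreb3, a gene of the B cell lineage, from 247 ± 5.2 to 63.4 ± 7.2 (log2 change -1.55). By day 2 Sprr2b stood at 9344 and Vpreb3 at 169, and a probe set of Actb, chosen after its values were seen, ran a like course, at 826 in uninfected tissue, 27.1 at 12 hours and 666 at day 2. On the first and second day 4 array Actb stood at 17.2 and 149.5, Vpreb3 at 40.8 and 67.8 and Sprr2b at 7046.6 and 8075.

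Further genes that rose at 12 hours were Adamdec1, a metalloprotease gene of the intestine, from 296 ± 55 to 904 ± 79, Pck1, a gluconeogenic enzyme, from 93.2 ± 4.3 to 299 ± 58, and Ppara, a nuclear receptor for fatty acids, from 79.5 ± 22 to 240 ± 12. Dnase1, a secreted nuclease, fell from 916 ± 42 to 274 ± 51. Tfcp2l1 and Notch1 rose by 1.30 and 1.24 on the called probe set, but another probe set of each gene gave -0.49 and -0.20. In all, 28 of 7453 probe sets passed the test, 19 higher and 9 lower, and 1264 had an unadjusted p under 0.05. With only the arrays of the 2 groups 607 passed, 305 higher and 302 lower, and without the first arrays of days 4 and 7, a fit added after the data were seen, 1006 passed, 526 higher and 480 lower. The count was 1 without any single uninfected or 12-hour array, 14 without either day 2 array, 316 without the first and 324 without the second day 7 array. Each of the 18 genes called by the naming rule lost its call without at least 1 array. Sgk1 stayed between 2.02 and 2.38, with an adjusted p of 0.13 and 0.057 without the first and second uninfected array and of 0.078 and 0.093 without the first and second 12-hour array.

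Of the fixed lists, 4 were called at 12 hours with camera, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry 5 lists were called. These included the fibroblast and matrix and the endothelial lists but not MHC class II or ribosomal protein genes (adjusted p = 0.15 and 0.29), and 3 that camera did not call, for type I interferon, smooth muscle and immediate early genes (adjusted p = 0.048, 0.012 and 0.027). The fibroblast and matrix genes moved upwards with a median of 0.43 over 24 measured members (adjusted p = 0.00021, and adjusted p = 0.46 with an estimated correlation). 1 member rose, Col4a1, a basement membrane collagen, from 175 ± 19 to 380 ± 32 (log2 change 0.99, adjusted p = 0.049), and 7 rose when adjusted over the list alone. The endothelial genes had a median of 0.36, with 3 of 14 members higher adjusted over the list alone (camera adjusted p = 0.048, and adjusted p = 0.46 with an estimated correlation). The ribosomal protein genes had a median of -0.30 (adjusted p = 0.02, and adjusted p = 0.66 with an estimated correlation), and the genes of antigen presentation by MHC class II a median of -0.27 (adjusted p = 0.033, and adjusted p = 0.46 with an estimated correlation). Without the second uninfected or the second 12-hour array 1 list was called, the fibroblast and matrix genes. The MHC class II, endothelial and ribosomal protein lists then had an adjusted p of 0.22 each without the former and of 0.34, 0.12 and 0.12 without the latter. The endothelial call was also lost without the first 12-hour array (adjusted p = 0.063) or either day 4 array (adjusted p = 0.07), and had an adjusted p of 0.05 without the second day 2 array. At 12 hours the probe sets of 1 gene disagreed with each other by 0.28 log2 units at the median, against 0.18 expected from the replicate arrays.

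By day 2, genes of innate inflammation had risen in Peyer's patches. S100a8 and S100a9, whose products form calprotectin in neutrophils, rose from 20.9 ± 0.42 to 1580 ± 110 and from 15.8 ± 0.85 to 781 ± 43. Il1b, which encodes interleukin-1 beta, rose by 4.66 (SE 0.28, adjusted p = 1.8e-05), from 24.9 ± 13 to 1390 ± 19. Mmp3, a protease that degrades extracellular matrix, rose from 23 ± 2.1 to 1050 ± 0.42, and Slfn4, a myeloid gene induced by interferon, from 54 ± 10 to 1550 ± 7.5. Hdc, the enzyme that makes histamine, rose from 2.2 ± 0 to 286 ± 18 (log2 change 3.21, adjusted p = 1.3e-05).

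The inflammatory cytokine and chemokine list rose at day 2, with 12 of 19 measured members up, 15 adjusted over the list alone, and a median of 1.72 (camera adjusted p = 2.4e-26). It held Cxcl2, which attracts neutrophils, from 11.2 ± 2.5 to 312 ± 1.9, and Ccl2, which attracts monocytes, from 12 ± 9.2 to 304 ± 42. Il1a rose from 22.8 ± 13 to 456 ± 130, and Il6 from 7.45 ± 2.3 to 118 ± 26. Of the neutrophil genes 8 of 12 rose, 9 adjusted over the list alone, with a median of 1.63 (adjusted p = 1.4e-17). Of the acute phase and antimicrobial genes 10 of 26 rose, 12 adjusted over the list alone, with a median of 0.59 (adjusted p = 4.8e-14). S100a8, S100a9 and Lcn2 stand on both of these lists. Saa3, an acute phase protein, rose from 31 ± 16 to 543 ± 98, and Acod1, the enzyme that makes itaconate in macrophages, by 3.43 (adjusted p = 2.2e-05). Lcn2, which binds bacterial iron carriers, rose from 7 ± 4.5 to 227 ± 49 (log2 change 2.72), but its other probe set gave -0.28 (adjusted p = 0.8).

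Genes that respond to interferon rose as well. Gbp2, a GTPase induced by interferon gamma, rose by 3.47 (SE 0.19, adjusted p = 1.3e-05), from 70.6 ± 4.7 to 1100 ± 1.3, and Iigp1, a GTPase that acts on pathogen vacuoles, from 70.8 ± 16 to 740 ± 65. The chemokine genes Cxcl9 and Cxcl10, which attract T cells, rose from 33.7 ± 9.2 to 321 ± 12 and from 20 ± 0.42 to 135 ± 4.5. In the interferon gamma list 10 of 25 members rose, 12 adjusted over the list alone, with a median of 0.58 (adjusted p = 1.7e-12). In the type I interferon list 6 of 19 rose, 7 adjusted over the list alone, with a median of 0.45 (adjusted p = 1e-07), among them the antiviral genes Rsad2 by 2.17 and Ifit2 by 2.11. Of the monocyte and macrophage genes 5 of 19 rose, 9 adjusted over the list alone, with a median of 0.43 (adjusted p = 1.7e-08). Arg1, an arginine-degrading enzyme, rose from 5.1 ± 0.42 to 170 ± 14, and Cd14, a receptor for lipopolysaccharide, from 258 ± 36 to 1380 ± 29. Of the fibroblast and matrix genes 7 of 24 rose, 14 adjusted over the list alone, with a median of 0.71 (adjusted p = 2.3e-14). Besides Mmp3 they included Mmp10 by 2.72, a further matrix protease, and Timp1, an inhibitor of such proteases, from 166 ± 2.4 to 1160 ± 320.

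Genes of the absorptive epithelium were lower at day 2. Cyp3a11, a drug-metabolising cytochrome P450, fell by 2.19 (SE 0.18, adjusted p = 0.00014), from 2570 ± 77 to 538 ± 11. Slc34a2 fell from 1320 ± 81 to 422 ± 15, Pdzk1, a scaffold for membrane transporters, from 641 ± 68 to 173 ± 30, and Rdh7, a retinol dehydrogenase, from 382 ± 0.35 to 108 ± 1.3. The other probe set of Pdzk1 gave -0.74 (adjusted p = 0.49), against -1.72 on the called one. Of the enterocyte genes 4 of 28 fell, 12 fell and 1 rose when adjusted over the list alone, and the median was -0.53 (camera adjusted p = 2.1e-10, and adjusted p = 0.077 with an estimated correlation). Lct, the enzyme lactase, fell from 1690 ± 79 to 678 ± 9.8 (adjusted p = 0.0056). Its call was lost without the first and second uninfected array (adjusted p = 0.059 and 0.085) and without the first and second day 2 array (adjusted p = 0.083 and 0.072). Fabp6, the bile acid carrier of the ileum, fell from 3980 ± 210 to 1130 ± 41 (adjusted p = 0.0047), a call lost without the second uninfected array (adjusted p = 0.069) or the first and second day 2 array (adjusted p = 0.067 and 0.055), and with an adjusted p of 0.05 without the first uninfected array.

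In all, 203 of 7453 probe sets were called at day 2, 137 higher and 66 lower, and 862 had an unadjusted p under 0.05. The count was 92 and 79 without the first and second uninfected array, 85 and 82 without the first and second day 2 array, and 344 and 347 without the first and second day 7 array. Of the 43 genes called by the naming rule 31 kept their call whichever array was left out, among them S100a8, Il1b, Mmp3, Slfn4, Gbp2, Saa3, Cxcl9, Il6 and Cyp3a11.

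Lists with fewer called members completed the picture at day 2, when 15 lists were called, 10 up and 5 down, 8 of them with an estimated correlation and 16 by fry. The cell cycle genes had a median of 0.25 over 39 members (adjusted p = 0.0011), with 0 members called by limma and 4 at an unadjusted p under 0.05, all higher. The complement genes had a median of 0.36 (adjusted p = 0.037, and adjusted p = 0.14 with an estimated correlation). Of the heat shock genes 2 of 14 rose, Serpinh1 by 1.38 and Hsph1 by 0.77, with a list median of 0.27 (adjusted p = 0.033, and adjusted p = 0.3 with an estimated correlation). Both genes lost their calls without either uninfected or either day 2 array, with adjusted p from 0.11 to 0.37, and Hsph1 also without any 12-hour or day 4 array, with adjusted p from 0.051 to 0.083. The B cell genes had a median of -0.26 over 20 members (adjusted p = 0.0033, and adjusted p = 0.057 with an estimated correlation), with 0 called by limma and 3 lower at an unadjusted p under 0.05. Adipocyte genes had a median of -0.38 over 6 members (adjusted p = 0.019, and adjusted p = 0.11 with an estimated correlation). Oxidative phosphorylation and ribosomal protein genes had medians of -0.16 and -0.15 (adjusted p = 0.021 and 0.048, and adjusted p = 0.53 for both with an estimated correlation). The fry test did not call the heat shock, oxidative phosphorylation or ribosomal protein genes (adjusted p = 0.074, 0.49 and 0.38).

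In those lists 4 calls depended on single arrays. Complement was lost without the first uninfected, second uninfected and first day 2 array (adjusted p = 0.098, 0.051 and 0.12), and heat shock without the first uninfected and second day 2 array (adjusted p = 0.098 and 0.069). Oxidative phosphorylation was lost without the second uninfected and second day 2 array (adjusted p = 0.088 and 0.069). Ribosomal protein genes were lost without these same arrays (adjusted p = 0.35 and 0.43) and without any 12-hour or day 4 array (adjusted p from 0.055 to 0.06).

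**Figure D2:**
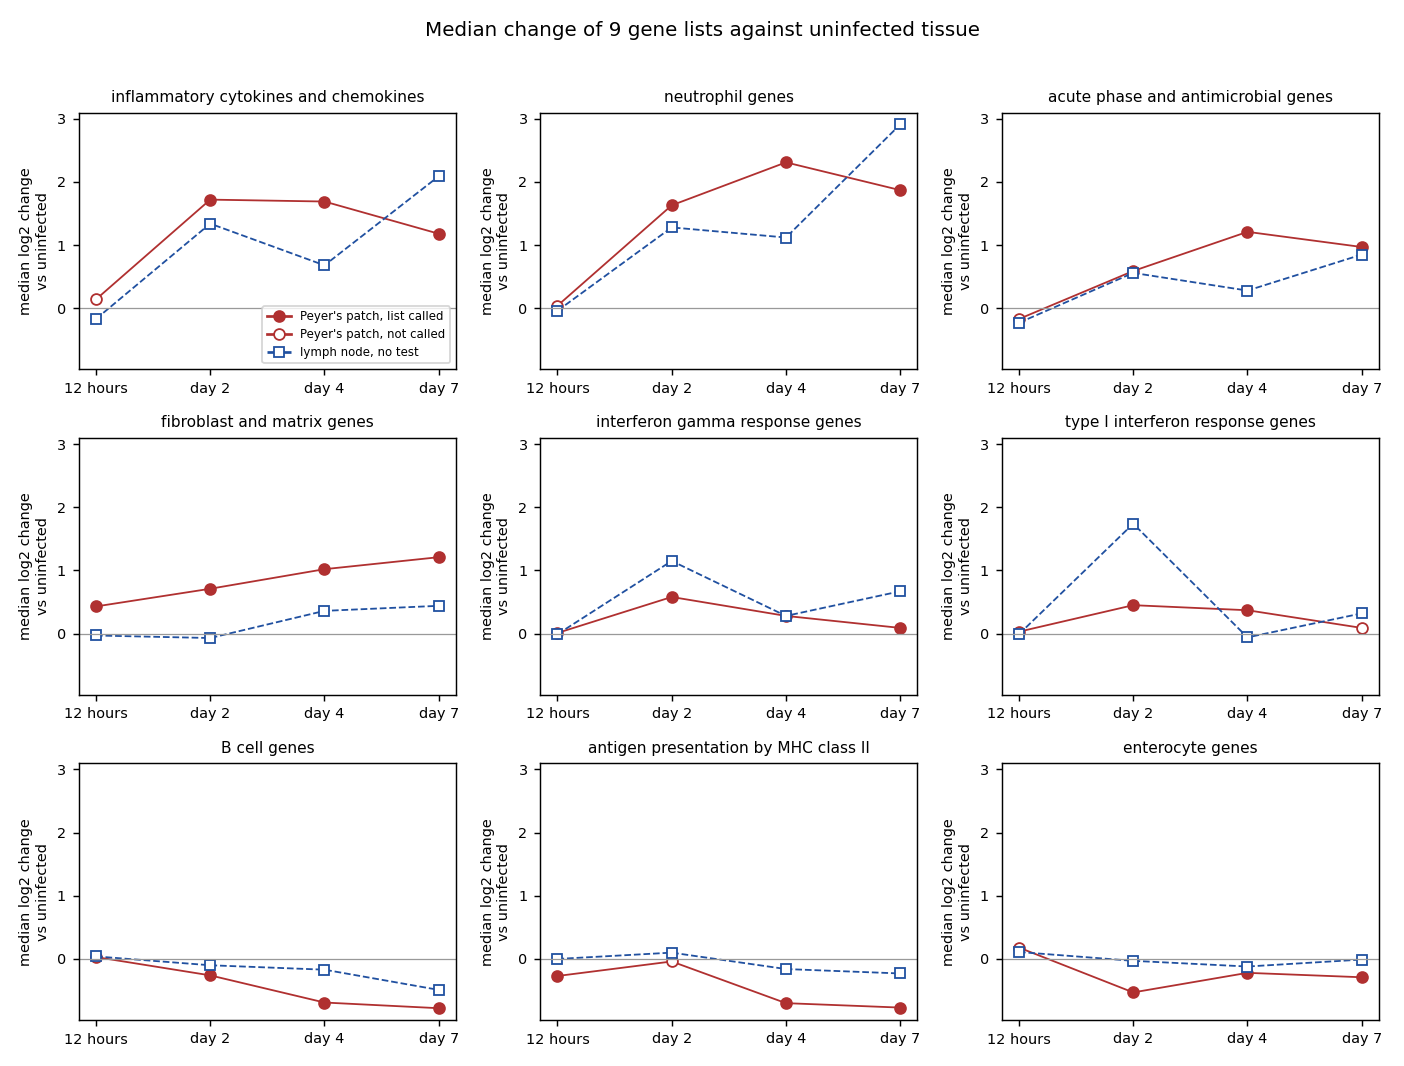
Median log2 change against uninfected tissue of 9 gene lists at 4 times. Red circles are Peyer's patches, filled where camera called the list, and dashed blue squares are the single lymph node arrays, which were not tested. In Peyer's patches the inflammatory list stood at 1.72 at day 2 and the B cell list at -0.78 at day 7.

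At day 4 neutrophil and acute phase genes were high in Peyer's patches, and B cell genes were low. S100a8 stood at 2990 ± 550 and Saa3 at 2800 ± 92, log2 changes of 5.82 (SE 0.28, adjusted p = 3.9e-06) and 5.51 (SE 0.31, adjusted p = 9.6e-06). Retnlb, a goblet cell product with antimicrobial activity, rose from 11.4 ± 4.5 to 774 ± 35 (log2 change 4.22, adjusted p = 1.8e-06). Plet1, which encodes an epithelial surface protein, rose from 34.2 ± 22 to 1700 ± 20, and Cxcl5, a neutrophil chemoattractant of epithelial cells, from 21.8 ± 3 to 717 ± 64. Vpreb3 fell from 247 ± 5.2 to 54.3 ± 19 (log2 change -1.71, SE 0.18, adjusted p = 0.00048), a level near its 63.4 at 12 hours, when the B cell list had a median of 0.03, with 169 at day 2 between.

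By list, 9 of 12 neutrophil genes rose at day 4, 10 adjusted over the list alone, with a median of 2.31 (camera adjusted p = 2.2e-16). Lcn2 rose by 5.01 to 1220 ± 150, although its other probe set gave 0.01, and Mmp9, a gelatinase of neutrophils, by 3.48. Of the inflammatory genes 12 of 19 rose, 16 adjusted over the list alone, with a median of 1.69 (adjusted p = 1.9e-20), including Il1b, at 1210 ± 380, and Cxcl2, at 506 ± 84. Of the acute phase and antimicrobial genes 13 of 26 rose, 18 adjusted over the list alone, with a median of 1.21 (adjusted p = 3.7e-15). Of the fibroblast and matrix genes 13 of 24 rose, 19 adjusted over the list alone, with a median of 1.02 (adjusted p = 2.8e-18). Col3a1, a fibrillar collagen, rose from 97.6 ± 12 to 529 ± 170 (log2 change 2.09, SE 0.29, adjusted p = 0.0025). Of the monocyte and macrophage genes 7 of 19 rose, 9 adjusted over the list alone, with a median of 0.49 (adjusted p = 2.8e-05), including Arg1, at 293 ± 2.8, and Cd14 by 1.99.

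Interferon gamma response genes were higher at day 4, with 9 of 25 up, 10 adjusted over the list alone, and a median of 0.28 (adjusted p = 4.5e-05). Gbp2 stood at 842 ± 130 and Cxcl9 at 328 ± 0.35. Of the type I interferon genes 4 of 19 rose, 6 adjusted over the list alone, with a median of 0.37 (adjusted p = 0.006, and adjusted p = 0.065 with an estimated correlation). Rsad2 rose by 1.31, a call lost without the second uninfected or the first day 4 array (adjusted p = 0.06 and 0.08). Among the endothelial genes Selp, the adhesion molecule P-selectin, rose from 6.4 ± 0.85 to 178 ± 45 (log2 change 2.43, SE 0.19, adjusted p = 6.3e-05). Of that list 4 of 14 rose, 8 rose and 1 fell adjusted over the list alone, with a median of 0.52 (adjusted p = 0.004, and adjusted p = 0.065 with an estimated correlation). The immediate early genes Ier3 and Dusp1, a phosphatase of MAP kinases, rose by 2.49 and 2.17, and 4 of the 20 listed rose, also 4 adjusted over the list alone (list median 0.21, adjusted p = 0.0042, and adjusted p = 0.065 with an estimated correlation). Of the NF-kB target and feedback genes 3 of 13 rose, also 3 adjusted over the list alone (median 0.15, adjusted p = 0.03, and adjusted p = 0.21 with an estimated correlation). These were Ier3, which stands on both lists, Tnfaip2 by 1.74 and Nfkbiz by 0.94. Tnfaip2 lost its call without the second uninfected array (adjusted p = 0.053), and Nfkbiz without the first uninfected, second uninfected and first day 4 array (adjusted p = 0.13, 0.087 and 0.085).

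Of the B cell genes 6 of 20 fell at day 4, 15 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 3.8e-11). Ms4a1, which encodes CD20, fell from 1840 ± 120 to 577 ± 190 (log2 change -1.66, SE 0.31, adjusted p = 0.015), and its other probe set by 1.64. Cd79b, a chain of the B cell receptor, fell from 1820 ± 140 to 806 ± 110 (log2 change -1.15, adjusted p = 0.0064). Of the MHC class II presentation genes 4 of 13 fell, 5 fell and 1 rose adjusted over the list alone, with a median of -0.70 (adjusted p = 9.6e-05, and adjusted p = 0.065 with an estimated correlation). H2-Aa, an MHC class II chain, fell from 5380 ± 370 to 2290 ± 160. The Ms4a1 call was lost without the first uninfected, second uninfected and second day 4 array (adjusted p = 0.1, 0.13 and 0.096), and the Cd79b call without the first and second uninfected array (adjusted p = 0.051 and 0.084). The H2-Aa call was lost without either uninfected or either day 4 array (adjusted p = 0.11, 0.15, 0.083 and 0.09).

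Single arrays were compared after these falls were seen. Against uninfected tissue the B cell list had medians of -0.01 and 0.04 on the 12-hour arrays, -0.67 and -0.73 on the day 4 arrays, and -0.69 and -0.85 on the day 7 arrays. The MHC class II list had medians of -0.14 and -0.38, -1 and -0.7, and -0.93 and -0.62. Single genes differed from the list and were chosen after their values were seen. Cd79a, a chain of the B cell receptor, stood at 955 and 749 on the 12-hour arrays, at 562.9 and 1062.6 on the first and second day 4 array and at 319.6 and 484.1 on those of day 7. Cd83 stood at 180.8 and 180.2, at 91.4 and 132.5 and at 22.3 and 73.2 on the same arrays, and at 289.5 and 254.2 at day 2. The cytoskeletal gene Cfl1, with a mean of 2990 in uninfected tissue, stood at 1380 and 2552 at day 4 and at 815 and 1084.9 at day 7. Actb, with a mean of 826, stood at 17.2 and 149.5 at day 4 but at 252.1 and 29.6 at day 7.

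The lymphoid organising chemokines and cytokines had a median of -0.35 over 14 members at day 4 (adjusted p = 0.012, and adjusted p = 0.085 with an estimated correlation), with 4 lower adjusted over the list alone. Cxcl13, which guides B cells into follicles, stood at 340 ± 56 against 420 ± 18 (adjusted p = 0.48). The T cell genes had a median of -0.24 over 16 members (adjusted p = 0.034, and adjusted p = 0.13 with an estimated correlation), and the T cell receptor component Cd3e a log2 change of -0.49 (adjusted p = 0.37). Of the enterocyte genes 2 of 28 fell and 1 rose, the same numbers adjusted over the list alone, with a median of -0.22 (adjusted p = 0.006, and adjusted p = 0.32 with an estimated correlation). The members that fell were Cyp3a11 and Lct. Lct fell by 1.05, a call lost without the first uninfected, second uninfected and second day 4 array (adjusted p = 0.091, 0.12 and 0.068). The member that rose was the keratin gene Krt18 by 1.13, a call lost without the first uninfected, second uninfected and first day 4 array (adjusted p = 0.14, 0.1 and 0.13). Cyp3a11 stood at 757 ± 74, Slc34a2 at 345 ± 52 and Fabp6 at 890 ± 130, each below its uninfected level. The oxidative phosphorylation genes, of which 1 of 30 fell (Atp5l, a subunit of the ATP synthase, by 0.83, lost without any array other than those of day 7, adjusted p from 0.083 to 0.26), had a median of -0.25 and the ribosomal protein genes a median of -0.32 (adjusted p = 0.00099 and 0.00086, and adjusted p = 0.36 and 0.26 with an estimated correlation). The fry test did not call the enterocyte, oxidative phosphorylation or ribosomal protein genes at this time (adjusted p = 0.084, 0.18 and 0.081).

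In all, 385 of 7453 probe sets were called at day 4, 290 higher and 95 lower, and 1284 had an unadjusted p under 0.05. The count was 147 and 157 without the first and second uninfected array, 241 without either day 2 array, 166 without the first day 4 array, and 657 and 658 without the first and second day 7 array. Of 58 genes called by the naming rule 37 kept their call whichever array was left out. Camera called 17 lists, 10 up and 7 down, 7 of them with an estimated correlation and 17 by fry. Without the second day 4 array the NF-kB, enterocyte, endothelial, oxidative phosphorylation and T cell calls were lost (adjusted p = 0.089, 0.12, 0.051, 0.072 and 0.06). The T cell call was also lost without the first uninfected array (adjusted p = 0.098), the first day 4 array (adjusted p = 0.07), and either day 7 array (adjusted p = 0.062 and 0.063). A probe set of Actb, the cytoskeletal beta-actin, stood at 83.4 ± 94 against 826 ± 190 (log2 change -3.17, adjusted p = 0.031). That call was lost without any array of the uninfected, 12-hour and day 2 groups or the first day 4 array (adjusted p from 0.057 to 0.22), and the gene's other probe set gave -1.56 (adjusted p = 0.39).

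At day 7 acute phase, neutrophil and matrix genes were high in Peyer's patches and B cell genes were low. Saa3 stood at 3010 ± 1400, Retnlb at 1470 ± 130 (log2 change 5.11, SE 0.17, adjusted p = 5.6e-07) and S100a8 at 1840 ± 860. Chil3, a chitinase-like protein of activated macrophages, rose from 10.4 ± 5.4 to 540 ± 120 (log2 change 3.74, SE 0.26, adjusted p = 3.6e-05). Cd79a fell from 1800 ± 71 to 402 ± 120 (log2 change -2.11, SE 0.29, adjusted p = 0.0026), and Vpreb3 from 247 ± 5.2 to 37 ± 1.8. Cd83, a surface protein of activated antigen-presenting cells, fell from 323 ± 50 to 47.8 ± 36 on the called probe set, and its other probe set gave -1.05 (adjusted p = 0.056). Cfl1 and Actb, chosen after their values were seen, gave -1.63 (adjusted p = 0.0087) and -2.68 (adjusted p = 0.051), with -0.36 on the other Actb probe set (adjusted p = 0.81). Of the monocyte and macrophage genes 6 of 19 rose, but the list was not called by camera (median -0.02, adjusted p = 0.13), while fry called it (adjusted p = 8.7e-05).

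Genes of pancreatic digestive enzymes also rose in both day 7 Peyer's patch arrays. Prss2, a trypsinogen, rose from 4.3 ± 0.85 to 1190 ± 420 (log2 change 5.03, SE 0.28, adjusted p = 8.4e-06), Cela2a, an elastase, from 69.1 ± 7.2 to 634 ± 160, and Cela1 from 138 ± 12 to 929 ± 170. Of the pancreas list 7 of 11 rose and 1 fell, with the same numbers adjusted over the list alone and a median of 1.97 (camera adjusted p = 9e-07, and adjusted p = 0.053 with an estimated correlation). The member that fell was Reg1 by 1.52. Reg2, of the same gene family, rose from 26.4 ± 24 to 1010 ± 220. Clps, the colipase, and Pnliprp2, a pancreatic lipase-related protein, gave 0.14 (adjusted p = 0.64) and 0.16 (adjusted p = 0.67). This rise stood beside every other day 7 change, and 487 of the 495 called probe sets at day 7 were outside the pancreas list. The list measured 11 genes, so some of those outside it may share the same source. 2210010C04Rik, which is not on it, went from 270 and 180.2 in uninfected tissue to 2439 and 1266 at day 7. From day 4 to day 7 its 2 probe sets, which can share sequence with other transcripts, rose by 2.73 and 1.54 (adjusted p = 0.011 and 0.037).

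**Figure D3:**
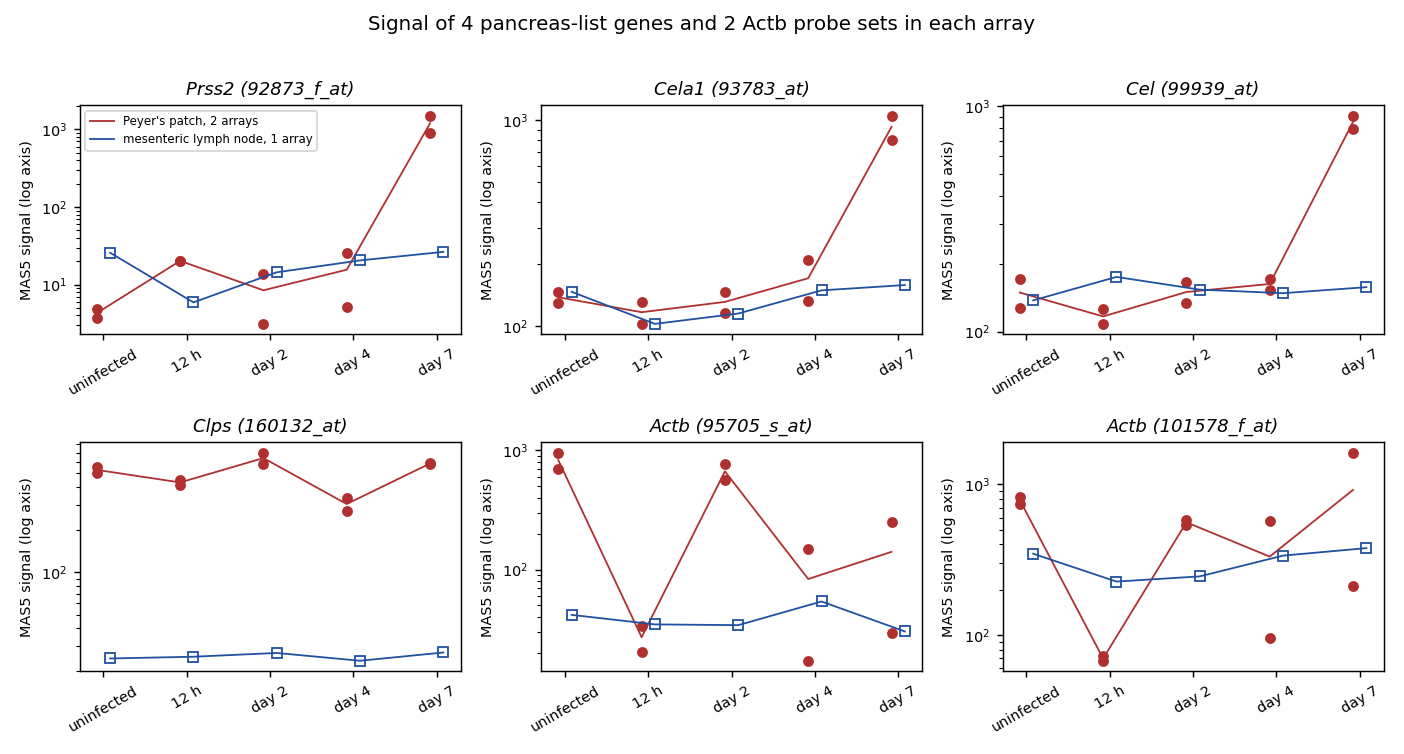
MAS5 signal (log axis) of 4 genes of the pancreas list and 2 Actb probe sets against time, with each Peyer's patch array as a red dot, a red line through their mean and the single lymph node array as an open blue square. In Peyer's patches Prss2 went from 4.3 in uninfected tissue to 1190 at day 7, and the first Actb probe set from 826 to 27.1 at 12 hours and 666 at day 2.

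Of the neutrophil genes 8 of 12 rose at day 7, also 8 adjusted over the list alone, with a median of 1.87 (camera adjusted p = 3.9e-10). Of the inflammatory genes 11 of 19 rose, also 11 adjusted over the list alone, with a median of 1.18 (adjusted p = 4.2e-11), among them Il1b, at 703 ± 190, and Cxcl5 by 3.17. Of the acute phase and antimicrobial genes 13 of 26 rose, and 17 rose and 2 fell adjusted over the list alone, with a median of 0.97 (adjusted p = 3.9e-10). Of the fibroblast and matrix genes 14 of 24 rose, 19 adjusted over the list alone, with a median of 1.21 (adjusted p = 3.9e-14), among them Mmp3, at 884 ± 120, Mmp10 by 2.65 and Col3a1 by 1.86. The Col3a1 call was lost without the first uninfected array (adjusted p = 0.063). Of the interferon gamma response genes 9 of 25 rose, and 10 rose and 1 fell adjusted over the list alone, with a median of 0.09 (adjusted p = 0.0019, and adjusted p = 0.053 with an estimated correlation). Gbp2 stood at 745 ± 140 and Cxcl9 at 353 ± 43 (log2 change 2.55, adjusted p = 2.4e-05).

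Of the B cell genes 8 of 20 fell at day 7, 14 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 1.2e-09), among them Cd79b, at 642 ± 86. Of the MHC class II presentation genes 4 of 13 fell, and 9 fell and 1 rose adjusted over the list alone, with a median of -0.77 (adjusted p = 5.5e-05, and adjusted p = 0.059 with an estimated correlation). H2-Ob, a modulator of peptide loading in B cells, fell from 485 ± 3.4 to 137 ± 49 (log2 change -1.64, adjusted p = 0.0018). Of the lymphoid organising genes 3 of 14 fell, 5 adjusted over the list alone, with a median of -0.52 (adjusted p = 0.0051, and adjusted p = 0.069 with an estimated correlation). Glycam1, a ligand for lymphocyte homing on high endothelial venules, fell from 320 ± 44 to 104 ± 7.2 (log2 change -1.36, SE 0.17, adjusted p = 0.0014). Ccr6, a chemokine receptor of B cells, fell from 616 ± 32 to 139 ± 93 (adjusted p = 0.0076), a call lost without the first and second uninfected array (adjusted p = 0.063 and 0.072). Cxcl13 gave -0.40 (adjusted p = 0.2) and Cd3e -0.31 (adjusted p = 0.47).

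Of the enterocyte genes 2 of 28 fell and 1 rose at day 7, 3 and 1 adjusted over the list alone, with a median of -0.29 (adjusted p = 0.012, and adjusted p = 0.42 with an estimated correlation), and Cyp3a11 stood at 524 ± 94. Lct fell by 1.21, a call lost without the first and second uninfected array (adjusted p = 0.053 and 0.066), and Krt18 rose by 0.85 (adjusted p = 0.049), a call lost without any array but the second of day 7 (adjusted p from 0.052 to 0.26). The smooth muscle genes had a median of -0.35 over 11 members, 5 of them lower adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.12 with an estimated correlation). Of the erythrocyte genes 2 of 6 fell, 3 adjusted over the list alone, with a median of -0.68 (adjusted p = 0.039, and adjusted p = 0.16 with an estimated correlation). These were the globin gene Hba-a1 by -1.22, a call lost without the first uninfected array (adjusted p = 0.11), and Car2 by -0.84, lost without either uninfected, either day 2 or the first day 7 array (adjusted p from 0.056 to 0.17). The ribosomal protein genes had a median of -0.36 (adjusted p = 0.012, and adjusted p = 0.42 with an estimated correlation). The fry test did not call the ribosomal protein genes (adjusted p = 0.087). Without the second uninfected array the enterocyte, smooth muscle, erythrocyte and ribosomal protein calls were lost (adjusted p = 0.085, 0.067, 0.085 and 0.11). Without the second day 7 array these calls and that of the interferon gamma list were lost (adjusted p = 0.39, 0.17, 0.27, 0.4 and 0.059).

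With only the arrays of the 2 groups compared, limma called 95 probe sets at day 7, 81 higher and 14 lower, against 607 at 12 hours and 625 at day 2. The rise of the reported counts over time thus depends on the spread shared by the 5 groups, although the day 7 arrays differed most. In that shared fit, 495 of 7453 probe sets were called at day 7, 334 higher and 161 lower, and 1874 had an unadjusted p under 0.05. The count was 143 and 168 without the first and second uninfected array, 296 and 295 without the first and second day 2 array, and 1887 without the second day 7 array. Of 47 genes called by the naming rule 33 kept their call whichever array was left out. Camera called 13 lists, 6 up and 7 down, 5 of them with an estimated correlation and 19 by fry. Without the second day 7 array 8 lists were called. The lists called with both the preset and the estimated correlation were the inflammatory, neutrophil, acute phase, fibroblast and matrix, interferon gamma, type I interferon, monocyte and macrophage, and cell cycle lists at day 2. At day 4 they were the neutrophil, inflammatory, acute phase, fibroblast and matrix, monocyte and macrophage, interferon gamma and B cell lists, and at day 7 the neutrophil, inflammatory, acute phase, fibroblast and matrix, and B cell lists.

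The comparison of neighbouring times asked when Peyer's patches changed. From 12 hours to day 2, S100a8 rose by 4.69 (adjusted p = 2.7e-05), Mmp3 by 4.59 (adjusted p = 1e-05) and Il1b by 4.02 (adjusted p = 6.3e-05). In the same step Sgk1 fell from 1340 ± 87 to 177 ± 12 (log2 change -2.72, SE 0.22, adjusted p = 0.00012) and Abcb1a from 945 ± 58 to 99.6 ± 11 (log2 change -2.89, SE 0.19, adjusted p = 5e-05). Cyp3a11 fell from 3140 ± 250 to 538 ± 11, and Usp2, a deubiquitinase with a daily rhythm in many tissues, from 292 ± 53 to 38.3 ± 28 (log2 change -2.26), although its other probe set gave -0.73 (adjusted p = 0.13). Sprr2c-ps, a pseudogene of the small proline-rich family, rose from 29.6 ± 6.1 to 757 ± 34 on a probe set that can share sequence with its relatives. Its uninfected signals were 674.7 and 429.9, so this was a return from a low at 12 hours. A probe set of Actb, which ran a like course, rose by 3.56 (adjusted p = 0.018), and the other gave 2.54 (adjusted p = 0.12). How many calls in this step were such returns was not counted. In this step 431 probe sets were called, 196 higher and 235 lower, and 1531 had an unadjusted p under 0.05. The count was 279 and 278 without the first and second uninfected array, 150 without either 12-hour array, 106 and 135 without the first and second day 2 array, and 905 and 904 without the first and second day 7 array.

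From day 2 to day 4, Saa3 rose from 543 ± 98 to 2800 ± 92 (log2 change 2.31, SE 0.31, adjusted p = 0.021), Retnlb from 154 ± 21 to 774 ± 35 (adjusted p = 0.0021), and Col1a1, the main fibrillar collagen, from 244 ± 10 to 774 ± 41 (log2 change 1.55, adjusted p = 0.0063). The other probe set of Col1a1 gave 0.53 (adjusted p = 0.56). Selp rose from 16.8 ± 0.35 to 178 ± 45 and Sgk1 from 177 ± 12 to 906 ± 210. Vpreb3 fell from 169 ± 3.3 to 54.3 ± 19 (log2 change -1.24, adjusted p = 0.029). In this step 22 probe sets were called, 19 higher and 3 lower, and 735 had an unadjusted p under 0.05. Without the first day 2 array limma called 0 probe sets, with 357 at an unadjusted p under 0.05, so each of these genes lost its call. The count was 3 without the second day 2 array, 4 and 8 without the first and second day 4 array, 6 without either uninfected array, 11 without either 12-hour array, and 108 and 111 without the first and second day 7 array.

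From day 4 to day 7, the 3 largest rises among the called genes were in genes of the pancreas list. Prss2 rose by 4.68 (adjusted p = 4.2e-05), Reg2 by 4.64 (adjusted p = 7.9e-05) and Cela2a by 2.9 (adjusted p = 7.8e-05). In the pancreas list 7 of 11 members rose and 1 fell, 8 and 1 adjusted over the list alone, with a median of 2.18 (camera adjusted p = 1.7e-17, and adjusted p = 0.034 with an estimated correlation). Camera called 9 lists in this step, 3 up and 6 down, 1 of them, the pancreas list, also with an estimated correlation. At an unadjusted p under 0.05 limma had 10 of 19 inflammatory, 5 of 12 neutrophil and 6 of 19 type I interferon genes lower, and 0 of each list higher. Slc34a2 rose from 345 ± 52 to 795 ± 120 (adjusted p = 0.039), and Slpi, an antiprotease of mucosal surfaces, fell by 1.33 (adjusted p = 0.0051) on the called probe set, while its 2 others gave -0.59 and -0.11 (adjusted p = 0.31 and 0.93). The Slpi call was lost without the second day 4 array (adjusted p = 0.062) and the Slc34a2 call without any single array other than the second of day 7 (adjusted p from 0.071 to 0.22). In this step 20 probe sets were called, 14 higher and 6 lower, and 743 had an unadjusted p under 0.05. The count was 13 without either day 2 array, 12 and 11 without the first and second day 4 array, and 823 without the second day 7 array. Prss2, Reg2, Cela1, Cela2a, Cel and Ctrb1 kept their calls whichever array was left out.

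The 2 tissues were compared over the 5 conditions, with the lymph node as the numerator and n = 5 conditions. Lymph nodes were higher in Marco, a scavenger receptor of macrophages, at 937 ± 180 against 7.14 ± 3.9 (log2 difference 4.62, SE 0.13, adjusted p = 3.7e-09), in Lyve1, a receptor of lymphatic endothelium, at 382 ± 91 against 45.5 ± 15, and in Glycam1, at 2150 ± 1200 against 271 ± 120. They were also higher in Adipoq, the fat cell hormone adiponectin, at 592 ± 500 against 22.5 ± 4.9, and in Cd3e, at 495 ± 95 against 152 ± 42 (log2 difference 1.55, adjusted p = 2.8e-05). Peyer's patches were higher in genes of the intestinal epithelium. Apoa1, an apolipoprotein of enterocytes, stood at 10600 ± 2300 against 10.5 ± 2.7 (log2 difference -7.94, SE 0.13, adjusted p = 4e-10), Reg3g, an antimicrobial lectin, at 6830 ± 1400 against 6.34 ± 0.89, and Fabp2, a fatty acid binding protein of the intestine, at 5010 ± 1400 against 6.74 ± 4.2.

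In the comparison of mesenteric lymph node vs Peyer's patch, 3739 of 7453 probe sets differed, 2429 (65%) of them higher in lymph nodes, and 4257 had an unadjusted p under 0.05. With each array centred on its median, which took out a shift of 0.17 log2 units between the tissues, 3342 differed and 50.1% were higher in lymph nodes. Of the epithelial lists, 28 of 28 enterocyte genes were lower in lymph nodes, also 28 adjusted over the list alone (median -4.75, camera adjusted p = 1.3e-29, and adjusted p = 0.12 with an estimated correlation), and 11 of 12 Paneth and goblet cell genes, also 11 adjusted over the list alone (median -4.91, adjusted p = 1.5e-11, and adjusted p = 0.053 with an estimated correlation). Of the T cell genes 20 of 21 were higher in lymph nodes, 21 adjusted over the list alone (median 1.33, adjusted p = 4.5e-08, and adjusted p = 0.31 with an estimated correlation). Of the MHC class II genes 12 of 13 were higher (median 0.67, adjusted p = 0.00077, and adjusted p = 0.5 with an estimated correlation) and of the adipocyte genes 8 of 11, with 1 lower (median 1.17, adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation). Camera called 18 lists, 12 higher and 6 lower in lymph nodes, and fry 24. With an estimated correlation camera called 0, with 5 at an unadjusted p under 0.05.

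Further lists higher in lymph nodes, each with the adjusted p of camera and then that with an estimated correlation, were monocyte and macrophage genes (median 1.09, adjusted p = 0.00011 and 0.34), endothelial genes (0.87, 0.00027 and 0.31), interferon gamma response genes (0.81, 0.00083 and 0.41), complement genes (1.10, 0.0027 and 0.34) and dendritic cell genes (0.93, 0.0029 and 0.31). The B cell genes (median 0.59, adjusted p = 0.017 and 0.5), NK and cytotoxic lymphocyte genes (0.68, 0.019 and 0.34), NF-kB genes (0.69, 0.022 and 0.5) and fibroblast and matrix genes (0.65, 0.044 and 0.69) were also higher. Lists lower in lymph nodes were oxidative phosphorylation genes (median -0.71, adjusted p = 4.2e-10 and 0.26), cholesterol synthesis genes (-0.96, 2.4e-05 and 0.34), smooth muscle genes (-1.14, 0.00011 and 0.12) and pancreas genes (-0.90, 0.00041 and 0.21). In the pancreas list 4 of 7 measured members were lower, with Zg16 at 18.7 ± 12 against 5190 ± 1200. The Peyer's patch values include day 7, when members of that list rose. Without the uninfected condition the fibroblast and matrix call was lost (adjusted p = 0.075), without day 2 the NK call (adjusted p = 0.051), and without day 7 the NF-kB call (adjusted p = 0.096).

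In the mesenteric lymph node, where each time had 1 array and no test was made, inflammatory genes stood higher from day 2. At day 2 Slfn4 stood at 1552.4 against 29.9 in the uninfected node, Il1b at 735.8 against 7.4, Saa3 at 1155.5 against 42.1, and Cxcl9 at 1998.9 against 145.5. At day 4 S100a8 stood at 1513.2 against 58.9. At day 7 Saa3 stood at 5655.6, Cxcl2 at 1705.5 against 3.1, Lcn2 at 2371 against 24.1, and Chil3 at 2835.1 against 79. Fcer2a, the low-affinity IgE receptor of B cells, stood at 211.3 against 1290.3 at day 7. Car3, a carbonic anhydrase abundant in fat and muscle, stood at 224.3 against 1801.2 at day 2, and Adipoq at 300.4 against 1346.9 at day 4. At 12 hours Timp1 stood at 313.3 against 67.7 and Alb, serum albumin, at 78.7 against 399.9.

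Probe sets at least 2-fold from the uninfected lymph node numbered 77 at 12 hours (30 higher), 327 at day 2 (205 higher), 171 at day 4 (111 higher) and 392 at day 7 (246 higher). At day 2 the type I interferon list had a median log2 ratio of 1.74, with 15 of 20 members at least 2-fold higher, while 95% of random lists lay between -0.25 and 0.11. The interferon gamma list had a median of 1.15 with 14 of 25 members at least 2-fold higher, and the inflammatory list one of 1.34 with 16 of 22. At day 4 the type I interferon median was -0.06, at the 31.8th percentile of random lists, and at day 7 it was 0.32, at percentile 100, with 6 of 20 members at least 2-fold higher. The neutrophil list had medians of 1.28, 1.12 and 2.91 at days 2, 4 and 7, with 10 of 14 members at least 2-fold higher at day 7. At day 7 the T cell and B cell lists had medians of -0.52 and -0.49, each at percentile 0 of random lists. The genes of the random lists were drawn independently, so such percentiles make no allowance for members that vary together and are not tests. The adipocyte list had medians of -0.83, -0.70 and -0.83 at days 2, 4 and 7. At 12 hours it was already lower, with a median of -0.34 at percentile 0.02, when the inflammatory list stood at -0.17. The ratios at every time share the single uninfected array, so the adipocyte medians are not independent observations of a fall after infection.

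Probe sets called in Peyer's patches were followed in the lymph node, which shares no control arrays with them. At day 2, 132 of 158 such probe sets (83.5%) moved in the same direction in the lymph node, against a mean of 53.9% (95% of draws between 46.2% and 61.4%) in 10000 random draws matched on mean signal. The shares were 239 of 322 (74.2%) at day 4, against a mean of 56.2% (50.9% to 61.5%), and 300 of 407 (73.7%) at day 7, against 55% (50.1% to 59.7%). At 12 hours 10 of 22 (45.5%) moved in the same direction, within the random range of 27.3% to 72.7%. These shares describe the arrays, since genes are not independent replicates.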

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

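The tests of pancreatic tissue, of a single-array fault, of expression by infected tissue, of transcript isoforms and of clock time were chosen only after the results they bear on were seen, and the reading of the ratio test for glucocorticoid genes was changed after its value was seen. The values below stood out because neighbouring times differed in a direct test, or because the log2 values of Peyer's patches and the lymph node had opposite signs, in which case the difference was not tested.

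Peyer's patches differed between neighbouring times at 431 probe sets from 12 hours to day 2, at 22 from day 2 to day 4 and at 20 from day 4 to day 7.

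Pancreas genes rose at day 7 in Peyer's patches, with list medians of -0.04, -0.02, -0.24 and 1.97 at 12 hours and days 2, 4 and 7. The tables argue against a fault of a single array, since the 2 day 7 arrays had medians of 2.28 and 1.86 over uninfected tissue. Pancreatic tissue dissected into the day 7 pool may explain a list median of 1.97, but it would bring its other abundant transcripts, and Clps gave 0.14, Pnliprp2 0.16 and Reg1 -1.52, from uninfected signals of 528, 44.2 and 2820. Clps and Pnliprp2 did not rise, while 7 of the 11 list members did. By the criterion used, such a lack of rise leaves pancreatic tissue open and does not exclude it. Each gene entered by 1 probe set, and that of Pnliprp2 lay near the filter limit of 37.5. The fall of Reg1 from a high signal could hide an added share. Pancreatic tissue stays open, since no pancreas sample was measured to show what signals its share would bring. Expression by the infected tissue itself stays open too, as the lymph node median of 0.06 at day 7 does not speak to a response of Peyer's patches alone.

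At 12 hours probe sets of 1 gene disagreed more than the arrays' noise allows, with a median of 0.28 log2 units over 552 pairs from 409 genes. That was 1.6 times the 0.18 expected from the replicate arrays, which argues against noise within groups as the whole cause. Across pairs the disagreement correlated with that between the 2 day 4 arrays at r = 0.62, in arrays that share none with it, which is consistent with a technical axis common to these arrays. Isoforms that change with infection stay open, since the disagreement at day 2 was 0.63 times that at 12 hours and 1.34 times its own noise. The disagreement was not confined to 12 hours, as it was 0.26 at day 4 and 0.4 at day 7 against uninfected tissue. No expectation from replicate arrays was computed for those times. Between the 2 day 7 arrays it was 0.53 and correlated with the 12-hour disagreement at r = 0.45, against -0.05 for the 2 day 2 arrays. Chosen after its values were seen, Actb gave 826 ± 190 in uninfected tissue, 27.1 ± 9.3 at 12 hours and 666 ± 140 at day 2 on 1 probe set (12-hour adjusted p = 0.062), and 784, 69.8 and 558 on the other (adjusted p = 0.14).

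A list of 11 genes that respond to glucocorticoids, made after the values were seen, had 3, 3, 6 and 7 members called in Peyer's patches at 12 hours and days 2, 4 and 7, all higher but Abcb1a at day 2 (-1.17), with Tat and Mt2 at an uncalled -1.24 and -0.75 at 12 hours, and medians of 0.59, -0.17, 1.23 and 1.85, against untested medians of -0.06, -0.31, 0.2 and 0.25 in the lymph node. The list's mean absolute change in the lymph node was 0.29, 0.58, 0.68 and 0.84 at these times. These values lay at percentiles 87.5, 96.2, 99.7 and 99 of random lists, so single members did move there from day 2. A different clock time of tissue collection may contribute. Of 13 clock genes, also listed after the values were seen, limma called 0 in Peyer's patches at 12 hours (lowest adjusted p = 0.065, for Usp2). Their mean absolute change was 0.57, at percentile 99.8 of random lists, a rank that decides little for genes picked in this way. Usp2 gave 1.47 and Nr1d2 1.28, while Nr1d1 gave -0.06 and Clock -0.16. Per1, which stands on both lists, gave 0.9 in Peyer's patches and -0.91 in the lymph node. Clock time stays open because the lymph node taken at the same time lay at percentile 86.8, and a response of the infected mouse was not tested. As for the disagreement between probe sets, the median ratio of the day 4 array difference to the 12-hour change was 0.21 over 3 called genes, under the limit of 0.25 set beforehand for excluding it. It is left open by a stricter reading adopted after that value was seen, which asks every gene to lie under the limit, since the ratios ran from 0.09 to 0.29 in genes chosen for the pattern.

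Genes called in Peyer's patches had a lymph node ratio of the other sign as follows, some of them so near 0 that the lymph node hardly moved, and none of it tested. The first 5 genes are from 12 hours. Zbtb16 gave 1.59 in Peyer's patches and -0.29 in the lymph node. Adamdec1 gave 1.52 and -0.23. Pck1 gave 1.39 and -0.39. Ptk2b gave 1.33 and -0.01. Notch1 gave 1.24 and -0.29, and its other probe set in Peyer's patches gave -0.2. At day 4 Ms4a1 gave -1.66 in Peyer's patches and 0.18 in the lymph node, and at day 7 Ccr6 gave -2.03 and 0.01.

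List medians over the members measured in both tissues also differed in sign, again untested and with some lymph node values near 0. At 12 hours the fibroblast and matrix genes had medians of 0.43 in Peyer's patches and -0.03 in the lymph node, and at day 2 of 0.67 and -0.07. The ribosomal protein genes had medians of -0.29 and 0.14 at 12 hours. The oxidative phosphorylation genes had medians of -0.17 and 0.05 at day 2 and of -0.26 and 0.08 at day 4. At day 4 the type I interferon genes had medians of 0.37 and -0.02, and the lymphoid organising genes of -0.29 and 0.05.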

How the results depend on the processing

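Of 189 recomputed counts and same-direction shares 150 stayed near the reported value and 39 did not, with the fits that left out an array not among them. A count was near if it lay within 1.5 times the reported one. A share was near if it lay in the 95% binomial interval of the reported share, which treats genes as independent. The fit of days 4 and 7 by their second arrays alone was chosen after the data were seen. Dim signals limit the ratios, as the pseudocount results show. Few arrays limit the precision, but their number was not varied alone, so its part in the other changes is not known. Unless stated, the cause of a change was not tested.

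At a threshold of 0.01, stricter by construction, the counts were 5 at 12 hours, 111 at day 2, 173 at day 4, 183 at day 7, 158 from 12 hours to day 2, 5 from day 2 to day 4, 12 from day 4 to day 7 and 218 at any time. With days 4 and 7 by their second arrays alone they were 1006, 544, 613, 756, 1507 from 12 hours to day 2, 36 from day 2 to day 4 and 1688 at any time, and the balance shifted, to 526 higher and 480 lower at 12 hours and 385 and 371 at day 7, against 19 and 9 and 334 and 161. With only the arrays of the 2 groups compared they were 607 at 12 hours, 625 at day 2, 95 at day 7, 1352 from 12 hours to day 2, 10 from day 2 to day 4 and 7 from day 4 to day 7, with 305 higher and 302 lower at 12 hours and 81 and 14 at day 7. From day 2 to day 4 a pseudocount of 8 gave 12. From day 4 to day 7 a pseudocount of 8 gave 13, one of 100 gave 35 and leaving out the dimmest 60% gave 12, with fewer probe sets tested.

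Lists called at 12 hours were 2 without a filter, 2 after quantile normalization and 0 with an estimated correlation. That correlation left 8 lists at day 2, 7 at day 4, 5 at day 7 and 0 between tissues. At 0 calls camera had 2 lists at 12 hours and 5 between tissues with an unadjusted p under 0.05, and fry called 5 and 24. Probe sets 2-fold from the uninfected lymph node numbered 153, 11 and 132 at 12 hours with pseudocounts of 8 and 100 and without a filter, 173 at day 2 with 100, 287 and 62 at day 4 with 8 and 100, and 226 at day 7 with 100.

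Leaving out 1 array gave 1 to 324 calls at 12 hours, 79 to 347 at day 2, 147 to 658 at day 4, 143 to 1887 at day 7, 106 to 905 from 12 hours to day 2, 0 to 111 from day 2 to day 4, 11 to 823 from day 4 to day 7 and 232 to 1940 at any time. Of 10 arrays left out in turn, 8, 6, 7 and 5 moved the count by over 1.5 times at 12 hours and days 2, 4 and 7, and 8, 10 and 5 did so in the 3 steps. At the 0, limma had 357 probe sets at an unadjusted p under 0.05. Called lists ranged over 1 to 5, 12 to 15, 13 to 19 and 8 to 15 at the 4 times. Leaving out a condition gave 3161 to 3455 probe sets and 17 to 18 lists between tissues. A group left with 1 array was assumed to vary like the others.

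The replicate number as a block gave 23, 193, 335 and 463 calls at the 4 times, 390, 19 and 18 in the steps, 452 at any time, and 5, 15, 17 and 13 lists, within 1.5 times the reported counts. Of 10 pairs of groups 1 had a correlation of deviations over 0.1 (0.48, between days 4 and 7), the lowest was -0.15, and 6 of 10 arrays correlated best with their own number, so the numbers do not pair the arrays.

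Values for single Peyer's patch genes kept direction and side of the threshold in 4795 recomputations, lost the call in 597, gained one in 61 and reversed in 9. Lists kept theirs in 1025 and lost it in 122, tissue genes in 388 and 9, and lymph node genes stayed in 389 and moved in 122. On another probe set, reversed values were -0.49 for Tfcp2l1 and -0.2 for Notch1 at 12 hours, -0.28 for Lcn2 and 0.33 for Rpl19 at day 2, 0.14 for Ica1 and -0.2 for Gadd45b at day 4, -0.18 for Lcn2 from 12 hours to day 2 and 0.08 for Ica1 from day 2 to day 4. Quantile normalization gave 0.03 for Rpl41 at day 2. A further 63 uncalled values of panel genes are not printed singly, a choice made after reversals were seen. Of their 1252 recomputations 1180 stayed, 24 gained a call and 48 reversed, over 25 values of at most 0.62 in size, 0 of them past the limma threshold after reversing.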

Other observations

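The count of splits that part all 5 conditions was chosen only after the results were seen, and the lists described were picked from the planned ones afterwards. Secretory and plasma cell genes did not move as lists in Peyer's patches, yet members went both ways. Of 12 Paneth and goblet cell genes 1 rose and 2 fell at day 4, and 2 rose and 2 fell at day 7, with list medians of 0.16 and -0.03 (camera adjusted p = 0.82 and 0.61), while fry called the list at day 7 (adjusted p = 0.032). Retnlb was the called member with the largest rise on that list at both times, by 4.22 and 5.11. Of 9 plasma cell and immunoglobulin genes 1 rose and 1 fell at day 4 and again at day 7, with medians of 0.11 and 0.38 (adjusted p = 0.93 and 0.56). The unfolded protein response genes had medians of 0.23, 0.26 and 0.19 at days 2, 4 and 7, not called by camera (adjusted p = 0.11, 0.11 and 0.5) but called by fry (adjusted p = 0.013, 0.0063 and 0.042).

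Several other immune lists were not called by camera in Peyer's patches at day 7. The dendritic cell genes had a median of -0.08 (camera adjusted p = 0.41), the NK and cytotoxic lymphocyte genes -0.02 (adjusted p = 0.98), the germinal centre genes -0.47 over 5 members (adjusted p = 0.2) and the genes of antigen presentation by MHC class I -0.04 (adjusted p = 0.98). The type I interferon genes had a median of 0.09 (adjusted p = 0.72), and the T cell genes -0.23 (adjusted p = 0.2, but adjusted p = 0.014 by fry). The cholesterol synthesis genes had a median of 0.21 (adjusted p = 0.17, but adjusted p = 0.017 by fry). From day 2 to day 4 the B cell list moved down, with a median of -0.5, 1 of 20 members called and 8 adjusted over the list alone (adjusted p = 5.9e-09, and adjusted p = 0.03 with an estimated correlation).

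Other splits of the 10 values in the comparison of tissues were counted, 100 of the 126 splits being drawn. For probe sets 1 split, the real one, gave as many as its 3739 and the highest other gave 2. For called lists 14 splits, the real one included, gave as many as the real 18, and the highest other gave 21. Neither count can decide about chance. With 5 values of each tissue, every other split holds unequal numbers of the 2 tissues on each side. It thus carries part of the tissue difference and does not show what chance alone would give. Most of these splits break the pairing by condition that the fit takes out. Only 14 of the 100 part all 5 conditions, too few for a share under 0.05, and among them the highest other gave 0 probe sets and 20 lists, where limma's real count was 3739 and camera's was 18.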
